A study of Nitrosomonas europaea ATCC 19718 with 9 samples.

How the data were processed

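The study measured transcript levels of Nitrosomonas europaea on 9 Agilent single-colour arrays, 3 each of control, exposed (50 ppm cerium dioxide nanoparticles) and recovered (12 h after removal of the particles) cultures. Per the labels, the scanned images were quantified with Agilent Feature Extraction 11.0.1.1. The deposited scanner files hold, for each spot, a processed intensity from which the background was subtracted, on a linear scale and not normalized between arrays. The deposited expression table holds raw intensities, which were checked to be means over the 6 spots of a probe. It also holds log2 values that the authors normalized between arrays, whose sorted columns nearly coincide, as after quantile normalization. The deposited tables of changed genes give a fold of at least 2.00 as a ratio without sign, with its direction. They also give the p-value and FDR of the authors' comparison with the control, with p-values up to 0.049, and the test behind them is not given in the sources used here. Gene symbols, locus tags, products and chromosome coordinates come from the deposited expression table. The annotation version is not given in the sources used here.

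The array holds 1 probe for each of 2436 genes, and 2402 of these genes are annotated and 922 have a symbol. The other 34 have no annotation in the deposited table, and 8 of them were tested and counted but are not named. Among the deposited lines 3 were empty, and their content is not reported here. Spots marked as outliers by the scanner software were left out, and 0 spots were saturated. The signal was taken as log2 of the processed intensity minus the 75th percentile of its array, and the 6 spots of a probe were averaged. A gene was tested if at least 3 of its spots were well above background on at least 3 of the 9 arrays, which left 2401 genes.

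A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), with 6 residual degrees of freedom. All tests were two-sided. The p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called when its adjusted p was under 0.05. The comparisons were exposed against control, recovered against control and recovered against exposed. Same-number replicates were not treated as pairs: after removal of group means their deviations correlated above 0.1 in 3 of 9 pairs and in 4 of 18 pairs with different numbers. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

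Before the data were examined, 22 gene lists were fixed by symbol, product or locus tag, and each was tested against all other genes with camera of limma, with a preset correlation between genes of 0.01, adjusted over the 22 lists. Lists needed at least 5 tested genes. Counts of changed members are given over all genes and adjusted over the list alone. camera with an estimated correlation and fry were run beside it. The toxin-antitoxin list took in 4 genes through the letters of their product names (prfA, prfB, prfC and lolD). Without them it held 9 genes and was not called either, with camera adjusted p of 0.639, 0.814 and 0.215.

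Genes were named by a rule also fixed before the data were examined, and 170 genes met it. For each comparison with control it takes the 8 genes of named product (a symbol, or a product other than hypothetical or unknown protein) with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, and 5 and 5 for recovered against exposed. It adds up to 3 called members of each list with the largest change, and a fixed set of genes of ammonia oxidation, nitrite reduction, carbon fixation, heat shock, oxidative stress and mercury resistance. Not all of them are printed. The probes of near-identical copies (amo, hao, cyc) cannot be told apart with certainty.

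The changes of exposed and recovered cells against the same controls were compared across genes with Pearson's r and Spearman's rho. Unchanged groups and their controls were simulated together 100 times, as independent arrays with the variances of the fit, to show what shared controls alone give. The measured control values were not used in it. The fit was tested on simulated data: of 100 genes shifted 2-fold it found 85%, 86% and 91% in the 3 comparisons, and of 100 shifted 1.5-fold 46%, 36% and 42%. False calls made up 6.43%, 4.69% and 5% of its calls. A shifted list was called in each comparison. The simulated values were normal and independent between genes and arrays, with the same variance in all groups, as the fit assumes. These rates therefore do not cover groups of unequal spread, dependent arrays or correlated genes, and do not check the calls on the measured arrays for them.

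Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile scaling, median centring, no filter on dim genes, genes well above background on all 9 arrays, a replicate block, only the 2 groups compared, eBayes with trend and robust, the slide as a block, the authors' normalized values, a fold of at least 2, limma's treat against a fold of 1.2, and leaving out each array in turn. Normexp used the median intensities of spot and local background, since the files lack the mean intensity. The median and the brightest of several probes had nothing to change, with 1 probe per gene. Alternatives chosen after seeing the data were the arrays of slide 1 only, arrays 1 and 2 of each group only, no structural RNA probes, the toxin-antitoxin list without the 4 genes above, and the slide alternatives for lists, named genes and overlap. With the slide as a block, exposed 1 alone carries the comparison of exposed with the other groups within a slide, and it is assumed to vary like the others. Within slide 1 it is the whole exposed group. Differences between replicates had an SD of 0.42 to 0.66 log2 in exposed, 0.19 to 0.43 in control and 0.14 to 0.21 in recovered cells. An adjusted p for exposed cells within slide 1 may therefore be too small.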

Results

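Transcript levels of Nitrosomonas europaea were measured on 9 single-colour Agilent arrays. This bacterium gains its energy by oxidising ammonia to nitrite and builds its carbon from carbon dioxide. Per the labels, 3 arrays held RNA of untreated cells from a stirred chemostat (control). Another 3 held RNA of cells from the same kind of reactor with 50 ppm of cerium dioxide nanoparticles, sampled when ammonia removal had dropped by 10% (exposed). The last 3 held RNA of such cells after the particles were removed and the cells were kept for 12 h in fresh medium (recovered). The design text calls the 3 cultures of each state biological replicates. The array carried 1 probe for each of 2436 genes, printed as 6 spots, and 2401 genes were tested. All changes below are differences of group means on the log2 scale, with the standard error (SE) of the limma fit, n = 3 arrays per group.

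The median signal of a spot was 288, 128 and 197 on the control arrays, 125, 91.8 and 116 on the exposed arrays and 194, 167 and 171 on the recovered arrays. Genes well above background numbered 2418, 2388 and 2402 in control, 2304, 1563 and 2299 in exposed and 2387, 2339 and 2265 in recovered samples. Exposed 2 was the dimmest array relative to its background, with 64.2% of genes well above it and a negative control signal of 8.63 against 1.44 to 3.19 on the other arrays. The gap between the 75th percentile and the median of the signals was 1.65 to 1.87 log2 on the exposed arrays and 1.39 to 1.42 on the 6 others, so the exposed signals were spread more widely. All control and recovered arrays and exposed 1 were printed on slide 1, and exposed 2 and 3 on slide 2. Replicates correlated at r = 0.97 to 1.00 across genes. The labels call them biological replicates, and they were counted as separate samples on that ground alone. Within a group, replicate 3 lay between the others for 88.1% of genes in control, 56.4% in exposed and 63.1% in recovered cells, where 33.3% would be even. The SEs and the counts of genes below take the 3 arrays of a group as independent, which was not tested. The median SE of a difference was 0.16 log2.

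The comparison of exposed with control cells asked which genes changed while the nanoparticles were present. Heat shock proteins and proteases were higher: 16 of the 18 listed genes rose, 1 fell and 1 was not called (adjusted over the list alone, also 16 and 1), with a list median of 1.78 log2. The chaperone gene dnaK (NE1949, position 2105296 to 2107230, minus strand) rose by 3.60 ± 0.10 log2, 12.1-fold, and the chaperonin gene groEL (NE0028, 34935 to 36578, plus strand) by 3.20 ± 0.12, 9.17-fold. The membrane protease gene htpX (NE1421, 1550895 to 1551776, plus strand) rose 25.4-fold (4.66 ± 0.12), the largest change in this list. The exception was NE0035, annotated as a second protease La, at -1.06. Against all other genes, camera gave an adjusted p of 5.01e-07 for this list, and an adjusted p of 0.102 with an estimated correlation between genes. Within slide 1, where exposed 1 is the only exposed array, the list stood 2.14 log2 above the median gene. That array is also part of the main test, so this value is not separate support.

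Genes for ammonia oxidation also rose, though not all of them. Of 13 listed genes 8 were higher, 3 lower and 2 not called (adjusted over the list alone, 8 and 4). amoC3 (NE1411, 1540634 to 1541458, plus strand), a copy of the ammonia monooxygenase subunit C gene that lies apart from the others, rose 54.3-fold (5.76 ± 0.10 log2, limma adjusted p = 1.2e-09). amoC1 (NE0945) rose 14.0-fold (3.81 log2, and 2.34 with the authors' values) and amoC2 (NE2064) 14.1-fold, and these copies are near identical, so their probes cannot be told apart with certainty. The subunit A gene amoA1 (NE0944) was higher by 2.34 ± 0.21 log2 and the subunit B gene amoB1 (NE0943) by 1.84 ± 0.29, but quantile scaling, which pulls the brightest genes of all arrays to common values, gave 0.74 and -0.15. The same holds for the cytochrome c-554 genes cycA3 (NE0960) and cycA2 (NE2042), with 1.64 and 1.33 log2 against 0.33 and 0.22, both then uncalled. The gene for hydroxylamine oxidoreductase, hao2 (NE0962, 1047032 to 1048744, minus strand), which carries the next step of the pathway, went the other way and fell by 1.34 ± 0.10 log2 (limma adjusted p = 2.78e-06). Its value was -2.29 under quantile scaling and -2.37 with the authors' values. It too belongs to a family of near-identical copies. The hydroxylamine-oxidising cytochrome P460 gene cyp (NE0011) was lower too, with uneven values of -1.81, -4.35 and -2.88 on the exposed arrays, 1 of them not well above background, against -0.17 to -0.07 in control cells. The list's camera adjusted p of 0.0408 was 0.701 under quantile scaling, 0.351 with normexp, 0.0826 with median centring, 0.115 within slide 1 and 0.801 with an estimated correlation. The list's mean minus that of other genes, 1.40 log2, was 0.36 under quantile scaling, 0.71 with normexp, 1.40 with median centring and 1.53 within slide 1. The call was also lost without exposed 1 (0.0704) and without exposed 2 (0.075), where this difference was 1.34 and 1.37.

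The largest rise among protein-coding genes with a named product was that of cphA (NE0922, 1003119 to 1005425, plus strand), which encodes cyanophycin synthetase, an enzyme that stores nitrogen as an arginine and aspartate polymer. Its signal was 82.7-fold higher in exposed cells (6.37 ± 0.11 log2, limma adjusted p = 1.2e-09), and 6.37 under quantile scaling too. Its neighbour NE0923, a second cyanophycin synthetase gene, was 36.6-fold higher. Next to this pair on the opposite strand lie aniA (NE0924), a multicopper oxidase gene of the nitrite reductase cluster, at 2.71 ± 0.18 log2, and the cytochrome c genes NE0925 and NE0926 at 3.00 ± 0.35 and 2.89 ± 0.33. A methionine sulfoxide reductase gene, NE1701, rose 16.5-fold (4.05 ± 0.17, and 2.77 with normexp), and the efflux pump gene NE0345, dim in control cells, rose 19.7-fold (4.30 ± 0.15, and 2.39 with normexp). The FtsJ gene NE0527 rose 19.2-fold (4.27 ± 0.24), and the SufC gene ycf16 (NE1449) of iron-sulfur cluster assembly rose 10.2-fold (3.35 ± 0.24). All limma adjusted p of these genes were between 1.2e-09 and 5.45e-05, and the values of the 3 exposed arrays lay apart from those of the 3 controls.

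Of the 8 genes of named product with the largest rise, the 7 others were structural RNA genes. The 16S ribosomal RNA probe was 514-fold higher (9.01 ± 0.39 log2), tRNAAla2 102-fold, tRNAMet3 90.1-fold, tRNAAla1 88.1-fold, tRNASer1 83.8-fold, tRNAPhe1 56.7-fold and tRNACys1 55.8-fold. As a set chosen after these values were seen, 40 of 41 tested tRNA probes rose and 0 fell, with a median of 3.99 log2 (camera p = 7.61e-21, and p = 0.0672 with an estimated correlation). Of the other structural RNAs, ffs was at 1.63 log2, tmRNA at 0.26, the 5S rRNA at -0.39, rnpB at -0.73 and the 23S rRNA at -1.03. All of these but ffs lay within 1.93 log2 of the brightest gene in control cells, and whether signals level off there was not tested.

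Of 68 genes for amino acid biosynthesis 49 fell, 5 rose and 14 were not called (adjusted over the list alone, 50 and 6), with a median of -1.01 log2. The list's camera adjusted p was 0.00106, and 0.801 with an estimated correlation. The methionine synthase gene metE (NE1436) fell by 3.65 ± 0.86 log2, but its value with the slide as a block was -1.80 and no longer called, and without exposed 2 it was -2.43. The histidinol dehydrogenase gene hisD (NE0872) fell by 2.63 ± 0.41 (-1.72 with the slide as a block). Among the 5 that rose were glyA (0.94), which links serine and glycine, and aroQ1 (0.72) of the shikimate pathway, named here after their values were seen. Of 39 genes for tRNA synthetases and translation factors 29 fell, 4 rose and 6 were not called (adjusted over the list alone, 29 and 5), with a median of -1.04. Its camera adjusted p was 0.0353, 0.0385 with the slide as a block, 0.0601 within slide 1 and 0.801 with an estimated correlation. The release factor gene prfA (NE1913) fell by 3.00 ± 0.36 and the glycyl-tRNA synthetase gene glyS (NE1186) by 2.46 ± 0.46 (-1.62 with the slide as a block). The 8 genes of named product with the largest estimated fall were each well above background on 2 or fewer of the 3 exposed arrays, so their exact sizes and order are uncertain. They were gatB (NE2073), which serves the amidation of charged tRNAs, at -3.92 ± 0.46, the pyruvate kinase gene pykA1 (NE0325) at -3.88 ± 0.54, the ribonuclease PH gene rph (NE0276) at -3.79 ± 0.32, the ubiquinone biosynthesis gene ubiB (NE1869) at -3.66 ± 0.11, metE, the phospholipid synthesis gene plsX (NE1645) at -3.56 ± 0.34, the glycine dehydrogenase gene NE0609 at -3.49 ± 0.33 and the membrane protein gene NE1605 at -3.43 ± 0.19. With normexp background correction, which shrinks the changes of dim genes, 6 of these falls were -2.04 to -1.66, and those of rph and ubiB were -1.18 and -0.61, no longer called. The calls of hisD (-0.43), prfA (-1.02) and glyS (-0.72) ended likewise.

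Sigma factor genes, which direct RNA polymerase to sets of promoters, went both ways, with 14 of 28 higher and 7 lower (adjusted over the list alone, also 14 and 7) and a median of 0.51 log2. The heat shock sigma factor gene rpoH (NE0584) rose 7.03-fold (2.81 ± 0.15). The extracytoplasmic function (ECF) genes NE1617 and NE1071 rose 12.2-fold each, and NE1217 8.53-fold, the last 2 at 2.40 and 1.97 log2 with normexp. The list's camera adjusted p was 0.0233, 0.0611 with the slide as a block, 0.115 within slide 1 and 0.801 with an estimated correlation. Its mean minus that of other genes was 1.04 log2, and 0.74 in both slide fits. Of 75 genes of transposases and mobile elements 27 rose, 13 fell and 35 were not called (adjusted over the list alone, 27 and 12), with a median of 0.28. Many of these are near-identical copies whose probes cannot be told apart. The transposase gene NE0134 rose 34.7-fold (5.12 ± 0.16). Their camera adjusted p was 0.00702, 0.0894 under quantile scaling, 0.196 with normexp, 0.115 within slide 1 and 0.801 with an estimated correlation, and within slide 1 the list's median turned to -0.16. Their mean minus that of other genes was 0.61, 0.38 under quantile scaling, 0.09 with normexp and 0.31 within slide 1.

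Ribosomal protein genes (29 of 56 lower, 9 higher; adjusted over the list alone, 29 and 8) had a camera adjusted p of 0.208 and a median of -0.56 log2, and those of the respiratory chain and ATP synthase (23 of 34 lower, 2 higher, the same over the list alone) had 0.07 and -0.85. Both lists were called lower under quantile scaling (5.45e-05 and 0.00275) and with normexp (4.12e-08 and 9.17e-08), and neither was called with an estimated correlation (0.846 and 0.801). The NADH dehydrogenase genes nuoM (NE1765) and nuoI (NE1769) fell by 2.47 ± 0.33 and 2.23 ± 0.19, and nuoM was at -1.33 with normexp.

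The remaining 14 lists were not called in this comparison. Genes of the Calvin cycle, which fixes carbon dioxide, were split, with 12 of 17 lower and 4 higher. The transketolase gene cbbT (NE0328) fell by 2.20 ± 0.18 log2. The Rubisco genes rbcL (NE1921) and cbbS (NE1920) were higher by 1.40 ± 0.26 and 1.04 ± 0.21, but at 0.52 and 0.02 and uncalled under quantile scaling. Oxidative stress defence had 11 of 24 higher and 9 lower. The superoxide dismutase gene sodB (NE0870) was lower by only 0.47 ± 0.10 and -0.13 with median centring, and the catalase gene katA (NE1886) at -2.06 ± 0.36 but 0.11 with normexp and -1.12 with the slide as a block. Nitrite and nitric oxide reduction had 5 of 15 higher and 7 lower, among the latter the nitric oxide reductase gene norB (NE2004) at -1.23 ± 0.18. This list's median (-0.49) and mean (0.03) differ in sign. Of the 6 mercury resistance genes 2 were higher and 3 lower. merC (NE0840) was higher by 1.11 ± 0.24 and merT (NE0842) lower by 0.77 ± 0.27, and merA (NE0839), the mercuric reductase gene, was at -0.79 ± 0.43 (limma adjusted p = 0.124). With normexp merT and merA turned to 0.60 and 0.38. merC lost its call there (adjusted p = 0.119) though its value was no smaller, at 1.27. With the slide as a block merA turned to 0.33 and merT was at -0.26 and uncalled. merT was also uncalled without control 2, control 3 or exposed 2 (-0.59, -0.76 and -0.47), and merA was called without exposed 1 (-1.35). The list's mean was -0.31, while camera placed it above other genes. Iron uptake and storage had 13 of 44 higher and 18 lower, metal and multidrug efflux 6 of 28 and 12, and peptidoglycan and cell division 8 of 40 and 24. The TCA cycle and glycolysis had 6 of 27 higher and 17 lower, DNA repair 4 of 24 and 16, and toxin-antitoxin systems 3 of 13 and 7. Flagella and chemotaxis had 10 of 40 higher and 13 lower, pili and secretion 6 of 36 and 24, outer membrane and lipid synthesis 12 of 54 and 28, and stringent, phosphate and nitrogen regulation 6 of 18 and 10. Adjusted over the list alone, the counts differed for efflux (6 and 11), DNA repair (4 and 17) and flagella (8 and 12). For the iron list the median (-0.13) and mean (0.11) also differ in sign.

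In all, 1779 of 2401 genes passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 645 higher and 1134 lower. At least 2-fold changes numbered 391 and 681. This split depends on the scaling, since it places the median gene at -0.37 log2. Median centring, which moves the median by 0.35, gave 851 higher and 859 lower, quantile scaling (0.25) gave 810 and 1001. With the authors' deposited normalized values the split was 803 and 966. The split also depends on dim genes. With the scaling unchanged, the 1559 genes well above background on all 9 arrays gave 619 higher and 591 lower, but a gene that fell below background in exposed cells is left out there because it fell. Normexp (0.76) gave 485 and 272, and 452 of the 1779 genes had the opposite sign there. With the slide as a block 1527 genes passed. The authors' deposited table for this comparison, limited to changes of at least 2-fold, lists 903 genes, 391 higher and 512 lower. Of these, 901 were tested here, 863 passed in the same direction at any fold and 3 had the opposite sign. With at least 2-fold required here too, 745 passed in the same direction, and 327 genes that passed so here were not listed.

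**Figure D1:**
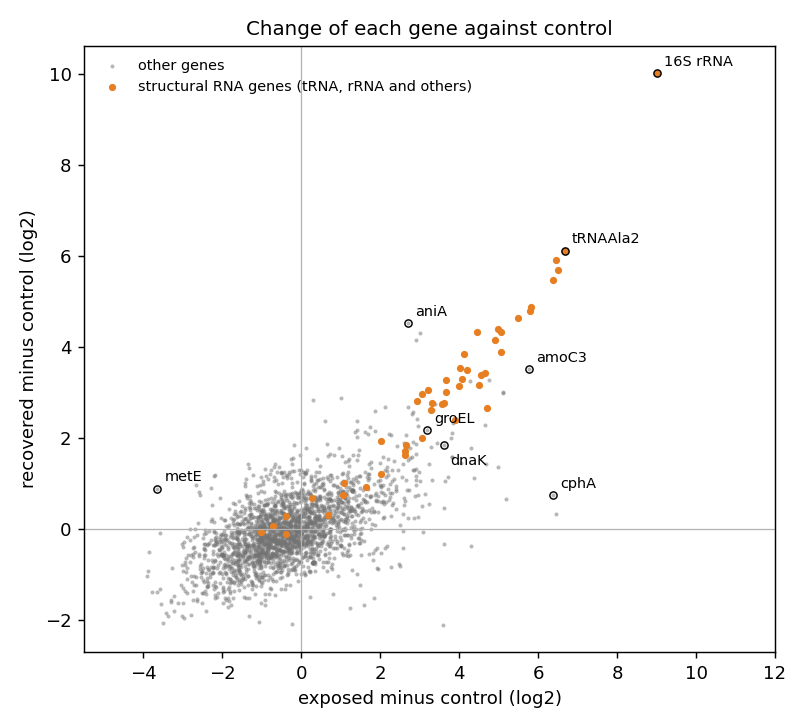
Each point is a tested gene, with its mean change in exposed against control cells on the x axis and in recovered against control cells on the y axis (log2, 3 arrays per group). Structural RNA genes are orange, with most tRNA genes at the upper right, the 16S rRNA at 9.01 and 10.01 and the 23S rRNA at -1.03 and -0.05, and cphA lies at 6.37 and 0.75.

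The comparison of recovered with control cells asked what differed after 12 h in fresh medium without nanoparticles. No array held RNA of untreated cells kept for 12 h in fresh medium. Earlier exposure, the medium and the time therefore cannot be told apart here. All control and recovered arrays lie on slide 1, so the slide fits do not test the slide in this comparison. They change only which exposed arrays add to the estimate of the spread. The nitrite reductase cluster stood out. aniA (NE0924, 1008210 to 1009139, minus strand) was 4.52 ± 0.18 log2 above control (limma adjusted p = 5.28e-07), NE0925 19.9-fold and NE0926 17.8-fold, all under quantile scaling too (4.36, 4.17 and 3.91). As a whole the list for nitrite and nitric oxide reduction, with 7 of 15 higher and 3 lower (the same over the list alone), was not called (camera adjusted p = 0.294), and norB was lower by 0.81 ± 0.18. The Rubisco genes rbcL and cbbS were higher by 2.03 ± 0.26 and 1.62 ± 0.21 (1.28 and 0.74 under quantile scaling). The Calvin cycle list had 6 of 17 higher and 4 lower and was not called (0.725).

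Heat shock proteins and proteases were still above control, with 9 of 18 higher, 1 lower and 8 not called (adjusted over the list alone, 9 and 1) and a median of 0.49 log2. groEL was higher by 2.18 ± 0.12, htpX by 2.29 ± 0.12 and dnaK by 1.86 ± 0.10. The list's camera adjusted p of 0.0274 was 0.12 under quantile scaling, 0.0556 within slide 1 and 0.699 with an estimated correlation. Its mean minus that of other genes was 0.62 log2, 0.47 under quantile scaling and 0.62 within slide 1. rpoH was 3.00-fold higher and rpoE1 (NE2331), a sigma factor gene of the envelope stress type, 2.99-fold (1.58 log2, and 1.02 under quantile scaling). The sigma factor list was not called (5 of 28 higher and 9 lower, camera adjusted p = 0.45).

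Genes for peptidoglycan and cell division were lower, with 23 of 40 down, 5 up and 12 not called (adjusted over the list alone, 25 and 5) and a median of -0.51 log2. murC (NE0992, 1078921 to 1080342, plus strand), which encodes a ligase of peptidoglycan precursor synthesis, fell by 1.54 ± 0.21 and the division gene ftsA (NE0996, 1083137 to 1084375, plus strand) by 1.51 ± 0.15. The FtsJ gene NE0527, which this list holds through its product name although FtsJ proteins modify RNA, was 9.63-fold higher. The camera adjusted p was 0.00503, 0.0143 within slide 1 and 0.329 with an estimated correlation. Amino acid biosynthesis genes were lower too, 33 of 68 down, 5 up and 30 not called (the same over the list alone), with a median of -0.45 and a camera adjusted p of 0.00492, 0.0143 within slide 1 and 0.863 with an estimated correlation. The glutamine synthetase gene glnA1 (NE0504) was 2.83-fold lower (-0.98 log2 and uncalled with normexp), and ilvC (NE1323) of branched-chain amino acid synthesis fell by 1.32 ± 0.12.

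Of the ammonia oxidation genes 8 of 13 were higher and 3 lower (the same over the list alone), and the list was not called (camera adjusted p = 0.238). amoC3 was still 11.5-fold above control (3.52 ± 0.10 log2, and 3.54 under quantile scaling). amoC1 and amoC2 were higher by 1.59 ± 0.28 and 1.58 ± 0.27 and amoA1 by 1.11 ± 0.21, none of them called under quantile scaling (0.54, 0.52 and 0.06). amoB1, cycA3 and cycA2 (0.99, 0.94 and 0.82) turned to -0.25, -0.06 and -0.17 there, and amoB1 was uncalled without control 2 (0.77) or recovered 2 (0.97). hao2 was 2.82-fold lower, and at -2.29 log2 under quantile scaling and -2.37 with the authors' values. Ribosomal protein genes had 23 of 56 higher and 10 lower (adjusted over the list alone, 24 and 10). Their camera adjusted p was 0.0637, and 0.863 with an estimated correlation. rplE (NE0413) was higher by 1.88 ± 0.18 and rplJ (NE2048) by 1.63 ± 0.19 (1.03 under quantile scaling). Among other genes the copper transporter gene copA (NE1019) was 3.36-fold higher, the TonB-dependent receptor gene NE2124 5.94-fold, ycf16 6.11-fold and a thioredoxin gene, NE2328, 3.10-fold. cphA was 1.68-fold above control. sodB was lower by 0.55 ± 0.10, while katA (-0.46 ± 0.36), merA (0.31 ± 0.43) and merT (-0.39 ± 0.27) did not pass the test (limma adjusted p = 0.316, 0.579 and 0.265).

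The 8 genes of named product with the largest rise were again structural RNAs, led by the 16S rRNA at 1030-fold (10.01 ± 0.39 log2) and followed by tRNAAla2 at 69.6-fold, tRNAAla1, tRNAMet3, tRNASer1, tRNAPhe1, tRNACys1 and tRNASer3 at 24.8-fold. Of the 41 tRNA probes 39 were higher and 0 lower, with a median of 3.15 (camera p = 1.8e-23, and p = 0.0547 with an estimated correlation). The genes of named product with the largest fall were NE0609 (-2.05 ± 0.33), the dihydrolipoamide dehydrogenase gene lpdA3 (NE2319, -1.95 ± 0.17), the ferredoxin gene NE1874 (-1.90 ± 0.30), the helicase gene hrpA (NE0833, -1.89 ± 0.27), the isoprenoid synthesis gene dxs (NE1161, -1.88 ± 0.17), NE1605 (-1.83 ± 0.19), the tRNA thiolase gene NE1490 (-1.70 ± 0.20) and the ECF sigma factor gene NE0980 (-1.67 ± 0.19). NE1874, hrpA and dxs lost the call with normexp (-1.26, -0.68 and -0.81).

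The other lists were not called, with camera adjusted p from 0.0927 to 0.814. tRNA synthetases and translation factors had 4 of 39 higher and 14 lower, the TCA cycle and glycolysis 1 of 27 and 9, DNA repair 5 of 24 and 12, and the respiratory chain and ATP synthase 7 of 34 and 4. Oxidative stress defence had 8 of 24 higher and 4 lower, metal and multidrug efflux 5 of 28 and 5, iron uptake and storage 9 of 44 and 9, and mercury resistance 1 of 6 and 0. Toxin-antitoxin systems had 2 of 13 higher and 4 lower, transposases 17 of 75 and 19, flagella and chemotaxis 9 of 40 and 8, and pili and secretion 4 of 36 and 9. Outer membrane and lipid synthesis had 12 of 54 higher and 17 lower, and stringent, phosphate and nitrogen regulation 6 of 18 and 7. Adjusted over the list alone, the counts differed for the TCA cycle (1 and 8), DNA repair (6 and 12), oxidative stress (8 and 5), iron (8 and 9), mercury resistance (0 and 0) and transposases (17 and 9).

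In all, 1174 genes passed the limma test, 591 higher and 583 lower, and 241 and 161 of them changed at least 2-fold. This count depends on the spread, which the fit pools with the exposed arrays. Differences between replicates had an SD of 0.42 to 0.66 log2 in exposed, 0.19 to 0.43 in control and 0.14 to 0.21 in recovered cells. A fit of only the 2 groups compared gave 1597 genes, 776 higher and 821 lower. Normexp gave 254 and 131, and quantile scaling 625 and 777. With the slide as a block 1335 genes passed, the same number as without exposed 1. The fit within slide 1 gave the same number as that of only the 2 groups. In both, the median change stayed at -0.04 log2, as in the main fit, so these counts differ through the spread and not through the slide. Arrays 1 and 2 of each group alone gave 435. The authors' deposited table for this comparison, limited to changes of at least 2-fold, lists 366 genes, 166 higher and 200 lower. Of these, 351 passed here in the same direction at any fold and 4 had the opposite sign. With at least 2-fold required here too, 303 passed in the same direction, and 99 genes that passed so here were not listed.

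**Figure D2:**
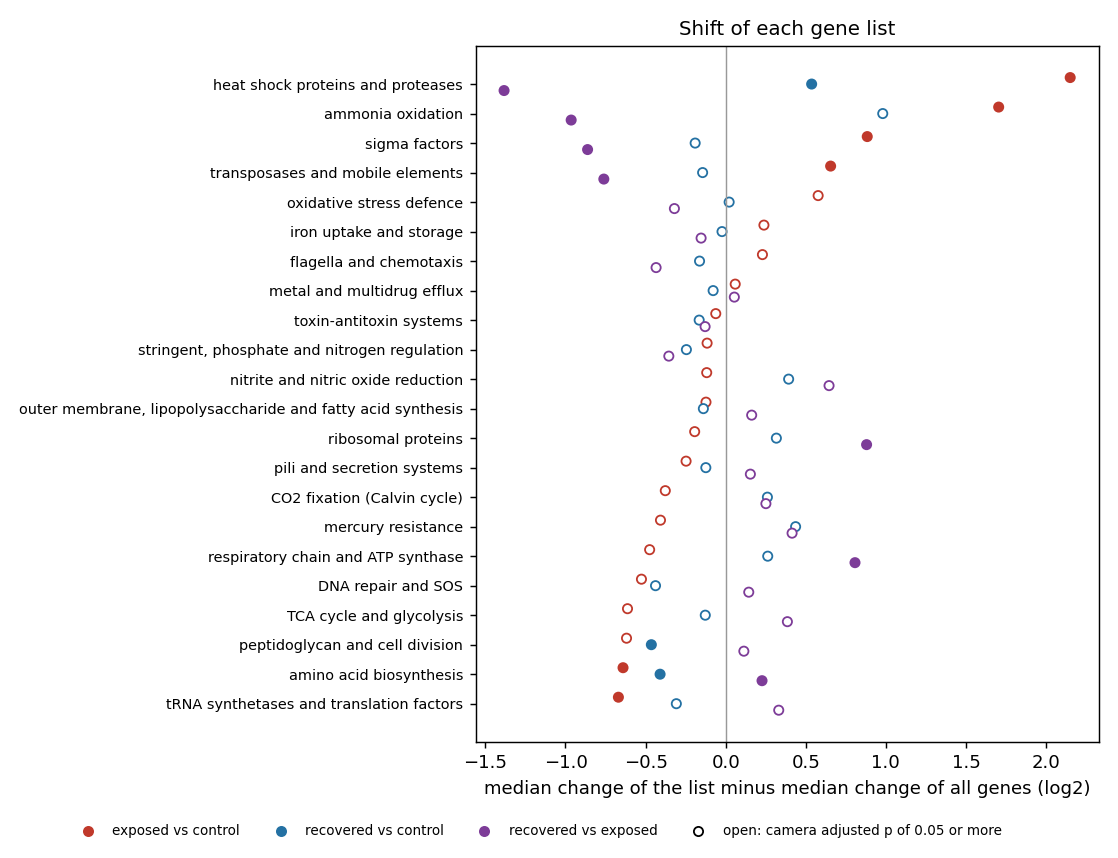
Each point is the median log2 change of a fixed gene list minus the median of all tested genes, for exposed against control (red), recovered against control (blue) and recovered against exposed (purple). Filled points have a camera adjusted p under 0.05 with the preset correlation, and heat shock proteins and proteases lie farthest to the right in exposed cells, at 2.15.

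The comparison of recovered with exposed cells asked what differed after the 12 h in fresh medium without nanoparticles. Removal of the particles, the medium and the time cannot be told apart here either. Genes for ribosomal proteins and for respiration rose. Of 56 ribosomal protein genes 39 were higher in recovered than in exposed cells, 7 lower and 10 not called (adjusted over the list alone, 41 and 7), with a median of 1.21 log2. rpsH (NE0415, 459961 to 460356, plus strand) rose by 2.39 ± 0.38, rpsQ (NE0410) by 2.23 ± 0.36 and rpsK (NE0424) by 2.17 ± 0.16. Of 34 genes of the respiratory chain and ATP synthase 26 rose and 1 fell (the same over the list alone), with a median of 1.13. Among them the cytochrome oxidase assembly gene ctaG (NE1015, 1101508 to 1102032, minus strand) rose by 2.37 ± 0.33, the oxidase subunit gene coxB (NE0684) by 2.28 ± 0.46 and nuoN (NE1764) by 2.20 ± 0.32. With the slide as a block rpsH, rpsQ, ctaG and coxB were at 1.34, 1.33, 1.51 and 1.26, coxB then uncalled, and nuoN was at 1.17 with normexp. Both lists had a camera adjusted p of 0.00392, and 0.718 with an estimated correlation.

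Heat shock proteins and proteases fell, 15 of 18 lower and 1 higher (the same over the list alone), with a median of -1.06 log2. Their camera adjusted p was 1.17e-06, and 0.116 with an estimated correlation. clpS (NE1732), a Clp protease adaptor gene, fell by 2.45 ± 0.14, htpX by 2.38 ± 0.12, dnaK by 1.74 ± 0.10 and groEL by 1.02 ± 0.12. Sigma factor genes fell, 14 of 28 lower and 6 higher (the same over the list alone), with a median of -0.54. Their camera adjusted p was 0.000693, and 0.718 with an estimated correlation. NE1071 fell by 3.93 ± 0.14, NE0980 by 3.27 ± 0.19 and NE1101 by 3.25 ± 0.26, all ECF genes. With normexp NE1071 and NE1101 were at -2.41 and -1.81. Transposases and mobile elements fell, 44 of 75 lower and 8 higher (adjusted over the list alone, 44 and 9), with a median of -0.43. Their camera adjusted p was 1.27e-05, and 0.718 with an estimated correlation. The transposase gene NE0134 fell by 2.12 ± 0.16.

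Ammonia oxidation genes were lower, 8 of 13 down and 2 up (the same over the list alone), with a median of -0.64 log2. amoC3, amoC2 and amoC1 fell by 2.24 ± 0.10, 2.23 ± 0.27 and 2.22 ± 0.28, cyp rose by 2.72 ± 0.50 (1.01 and uncalled with normexp, 1.52 with the slide as a block), and hao2 was at -0.16 ± 0.10 (limma adjusted p = 0.16). The camera adjusted p of 0.0201 was 0.302 under quantile scaling, 0.639 with normexp, 0.0627 without exposed 1 and 0.718 with an estimated correlation. The list's mean minus that of other genes, -0.79, was -0.39 under quantile scaling, -0.19 with normexp and -0.72 without exposed 1. Amino acid biosynthesis genes rose, 39 of 68 up and 9 down (the same over the list alone), with a median of 0.55 and a camera adjusted p of 0.0449. It was 0.0758 with median centring, 0.0541 with the slide as a block and 0.718 with an estimated correlation, and normexp turned the median to -0.02. Without exposed 1, recovered 1 or recovered 3 it was 0.0666, 0.0543 and 0.0579. The list's mean minus that of other genes, 0.42, was then 0.46, 0.41 and 0.41, and it was 0.42 with median centring and 0.35 with the slide as a block.

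The 5 genes of named product with the largest estimated rise were metE (4.55 ± 0.86 log2), tyrA (NE0337, 3.38) and pheA (NE0335, 3.33), both of aromatic amino acid synthesis, SCO1 (NE0509, 3.37), of cytochrome oxidase copper insertion, and the polysaccharide deacetylase gene NE1800 (3.18). Each was well above background on 2 of the 3 exposed arrays, so their exact sizes and order are uncertain. With normexp metE, pheA, SCO1 and NE1800 were at 2.65, 1.25, 1.87 and 1.58, and tyrA lost its call (0.88). metE and pheA were at 2.70 and 2.12 with the slide as a block, and metE was at 3.32 without exposed 2. cphA fell by 5.62 ± 0.11 log2 to 49.3-fold below its exposed level, and NE0923 and the M48 peptidase gene NE0076 were at -4.54 ± 0.16 and -3.62 ± 0.10. NE0345 was lower too, but well above background on only 1 of the 3 recovered arrays, so the size of its fall is uncertain (-4.66, and -2.31 with normexp). With NE1071 these were the 5 genes of named product with the largest estimated fall. aniA and rbcL did not come down, at 1.82 ± 0.18 (limma adjusted p = 3.85e-05) and 0.62 ± 0.26 (limma adjusted p = 0.0553), and rbcL was called as higher without control 1, control 2 or exposed 1 (0.62, 0.62 and 0.83). The tRNA probes had 0 higher and 27 of 41 lower (camera p = 1.73e-07, and p = 0.262 with an estimated correlation). katA was higher by 1.60 ± 0.36, merD (NE0838) by 1.68 ± 0.34 and merA was 2.14-fold higher, but normexp turned them to -0.32, -0.30 and -0.12, and with the slide as a block katA was at 0.66 and merA at -0.02, both uncalled. merA kept its call only without control 1 or exposed 1 (1.66 without the latter) among the fits that leave out 1 array.

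**Figure D3:**
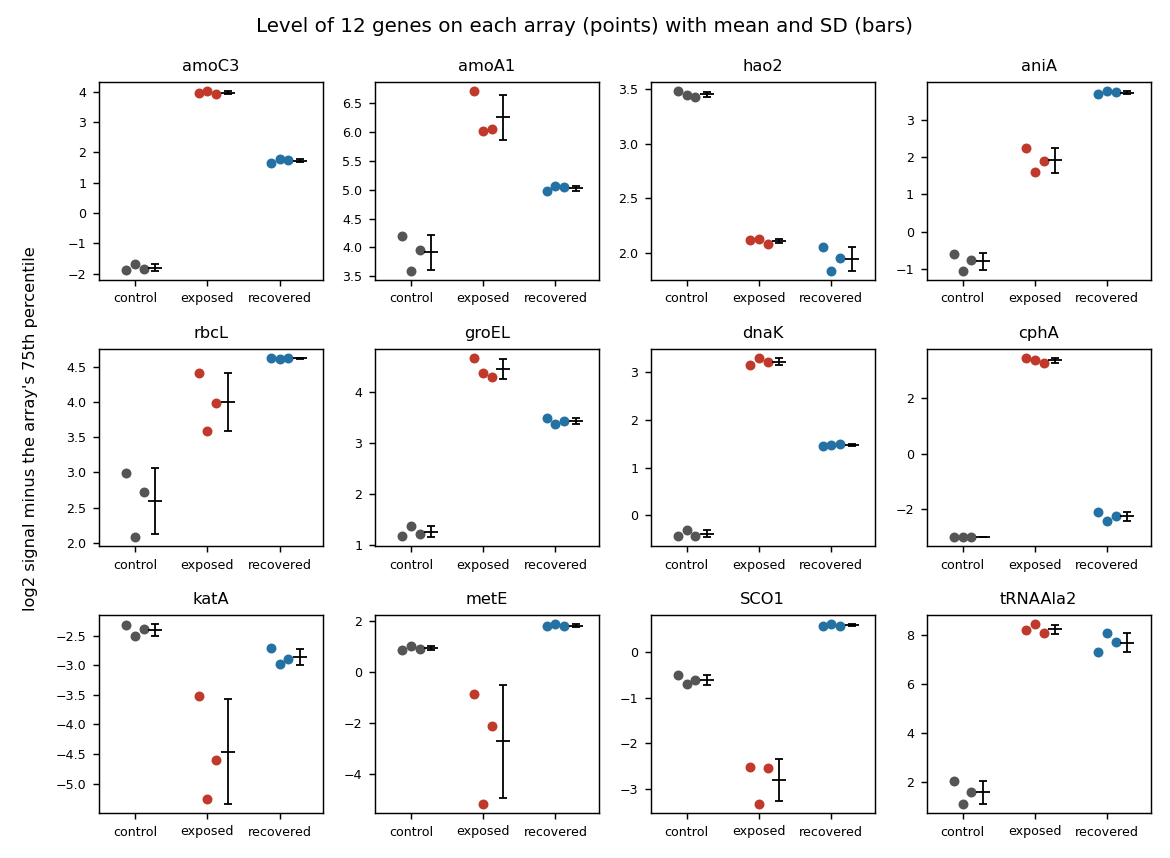
Scaled log2 signal of single genes on each of the 9 arrays (points) with the mean and SD of each group, on a log2 axis relative to each array's 75th percentile. cphA is highest in the 3 exposed samples, aniA is highest in the recovered samples, and dnaK, groEL and amoC3 lie between in the recovered samples.

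Lists not called in this comparison had camera adjusted p from 0.107 to 0.902. Calvin cycle genes had 11 of 17 higher and 1 lower, nitrite and nitric oxide reduction 10 of 15 and 1, tRNA synthetases and translation factors 23 of 39 and 5, and the TCA cycle and glycolysis 15 of 27 and 6. DNA repair had 14 of 24 higher and 2 lower, outer membrane and lipid synthesis 29 of 54 and 11, pili and secretion 20 of 36 and 4, and peptidoglycan and cell division 24 of 40 and 10. Iron uptake and storage had 18 of 44 higher and 13 lower, metal and multidrug efflux 9 of 28 and 4, mercury resistance 3 of 6 and 1, and oxidative stress defence 9 of 24 and 7. Flagella and chemotaxis had 10 of 40 and 10, toxin-antitoxin systems 5 of 13 and 4, and stringent, phosphate and nitrogen regulation 6 of 18 and 6. Adjusted over the list alone, the counts differed for DNA repair (13 and 2) and flagella (9 and 10). In all, 1651 genes passed the limma test, 1078 higher and 573 lower in recovered cells. Median centring gave 771 and 841, quantile scaling 863 and 799, and normexp 222 and 309. With the slide as a block 1262 genes passed.

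Of the 1779 genes called in exposed cells, 819 were also called in the same direction after recovery, 391 higher and 428 lower, where independent lists would share 159 and 275. The lists are not independent, since both comparisons use the same controls. Simulated unchanged groups shared at most 0 such calls, but the simulation held no changed genes, so it does not give the number to be set beside the 819. With normexp 275 were shared in all, and with arrays 1 and 2 of each group only 329. A further 829 were not called after recovery, and 131 were called in the opposite direction. A missing call does not show a return to control. A fit of only the control and recovered arrays called 1597 genes between them, where the fit to all arrays called 1174. By the direct test of recovered against exposed cells, 719 of the 829 and 493 of the 819 moved toward control, all 131 moved to its other side, and 53 of the 1779 moved further away. These genes were chosen on the same exposed arrays, so error in those arrays alone favours a move back, and its share was not simulated. Across genes, which are not independent replicates, the changes of exposed and recovered cells against control correlated at Pearson r = 0.68 and Spearman rho = 0.57. Simulated unchanged groups with shared controls gave r = 0.50 and rho = 0.47. This simulated r follows from the equal group sizes whatever the size of the noise, so it does not measure the share of the controls in the 0.68. The covariance was 0.876 against a simulated 0.0207. Noise in the shared controls, simulated as independent arrays, thus gave only a small part of the covariance. An error common to the 3 control arrays was not simulated, and they are too few to be split between the comparisons. Such an error may therefore still add to the overlap. Without structural RNA probes r was 0.60, and within slide 1 it was 0.73.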

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

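The slide and scaling tests of the tRNA and heat shock patterns below and the test on other structural RNAs were chosen after the result was seen, and the slide values of the opposite changes come from an alternative added later. A set of 131 genes stood apart because it was called in opposite directions against control in exposed and recovered cells, 57 higher in exposed and lower in recovered cells and 74 the reverse. The same direct test between recovered and exposed cells marked single genes whose changes against control pointed in opposite directions. Recovered minus exposed log2 values were 3.38 for tyrA, 3.37 for SCO1, 2.23 for rpsQ, 2.17 for rpsK and 2.04 for infA. They were 2.07 for cheY, 2.07 for NE2038, 1.75 for cbbQ, 1.52 for yxiE and 1.28 for NE1181, and -3.30 for NE0354, -3.27 for NE0980, -3.25 for NE1101, -2.40 for exbB1 and -1.79 for NE1233. With normexp tyrA and NE2038 were at 0.88 and 0.84, both uncalled, cbbQ at 0.85, SCO1 at 1.87 and NE1101 at -1.81, and rpsQ was at 1.33 with the slide as a block. Groups of 3 arrays were not tested for outlying samples.

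Of the 57 genes higher in exposed and lower in recovered cells, at least 98.2% kept their opposite signs under every scaling, and of the 74 with the reverse pattern 67.6% (normexp). Within slide 1 100% of both kept them, but the genes were chosen for these signs on the same arrays, with exposed 1 alone for the exposed cells on that slide, so these tests decide nothing. As calls in opposite directions 6 of the 57 and 9 of the 74 were left with normexp, 53 and 38 under quantile scaling and 49 and 35 with median centring. Scaling and slide therefore cannot be told apart from a change in the cells, and no biological explanation was tested. The number called also rests on single arrays: it was 73 without control 3, 83 without recovered 3, 197 without exposed 2 and 221 without exposed 1. With arrays 1 and 2 of each group only it was 15.

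The tRNA probes rose in exposed and recovered cells. In recovered against control cells, all on slide 1, their median was 3.15 log2, and the lowest median over all scalings and both comparisons was 2.85, which argues against slide as the cause in recovered cells and against scaling in both. In exposed cells the slide stays open, since the 3.46 log2 within slide 1 rests on exposed 1 alone. More structural RNA of every kind in the RNA or its labelling stays open too, because only 1 of the 5 other structural RNAs lay far below the brightest gene in control cells and whether signals level off there was not tested. This one, ffs, was at 1.63 log2 in exposed and 0.94 in recovered cells. Of the bright ones, tmRNA was at 0.26, the 5S rRNA at -0.39, rnpB at -0.73 and the 23S rRNA at -1.03 in exposed cells. A rise was thus not measured for every kind there. In recovered cells these were at 0.68, 0.30, 0.07 and -0.05. No biological explanation was tested.

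Heat shock genes stood above other genes in exposed cells. The median of the list minus that of all genes was at least 1.05 log2 under every scaling and with the authors' values, which argues against scaling. The list's median of 1.78 log2 lay at percentile 99.97 of 10000 random lists matched on mean level, the highest of which reached 2.18. This argues against the wider spread of the exposed signals. The random lists drew genes singly, however, so correlation within the list was left out of this test. The slide stays open, because the 2.14 log2 within slide 1 rests on exposed 1 alone, so slide and a response of the cells cannot be told apart. Over the alternatives tested with camera the adjusted p ranged from 1.65e-07 (without control 2) to 0.102 (with an estimated correlation).

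Only 10 splits of 6 arrays into 3 and 3 exist, so the share of splits with a result as large cannot go under 0.1. The gene counts by limma of 1779, 1174 and 1651 were each reached by 1 split, the real one, and the highest of the other splits was 0. Every other split mixes arrays of both states, so a difference between the states enlarges its spread and lowers its count. These gene counts therefore decide nothing about chance. The list counts of 6, 3 and 7 were reached by 3, 7 and 2 splits, with 7 as the highest of the others in each comparison.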

How the results depend on the processing

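The settings with slide 1 only, arrays 1 and 2, no structural RNA and, for lists, overlap and named genes, the slide block were chosen after seeing the data. Of 254 calls of named genes 162 were kept under all scalings, 247 without any 1 array and 230 never changed sign. Of 16 list calls by camera 11 were kept under all scalings, 13 without any 1 array, and 0 with an estimated correlation. The dim signal over background of exposed 2 limits what can be said of dim genes. With a replicate block 252 gene calls and 16 list calls were kept.

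Without 1 array the gene counts ranged from 1637 to 1864 (exposed against control), 901 to 1485 (recovered against control) and 1464 to 1761 (recovered against exposed), shared calls from 656 to 1009, r from 0.65 to 0.71 and list calls from 5 to 7, 3 to 4 and 5 to 8. Lists not called otherwise were called by camera without control 2 (respiratory chain in exposed cells, 0.0295, and TCA cycle in recovered cells, 0.046), without exposed 1, exposed 2 or recovered 1 (ribosomal proteins in recovered against control cells, 0.034, 0.0346 and 0.0249) and without exposed 2 (flagella between recovered and exposed cells, 0.0429). With only the 2 groups compared, 1644, 1597 and 1597 genes passed in the 3 comparisons. Normexp gave 757, 385 and 531 genes, 275 shared calls, 10 lists for exposed and 5 for recovered against control. At least 2-fold changes numbered 1072, 402 and 824, which a stricter threshold makes fewer, and treat gave 757 genes for recovered against control. Arrays 1 and 2 alone gave 435 genes there and 329 shared calls. Whether fewer samples or the loss of replicate 3, which often lay between the others, lowered these counts was not tested. r was 0.69 under quantile scaling, 0.70 with all 9 arrays above background and with the authors' values, 0.73 with the slide as a block and within slide 1, and 0.60 without structural RNA. Lists called for exposed against control were 3 with the slide as a block and 2 within slide 1, and 11 for recovered against exposed with all 9 arrays above background. With an estimated correlation they were 0, 0 and 0, with fry 16, 10 and 17, and with its mixed test 22, 21 and 22. The fry tests ask whether a list changed at all, and camera whether it changed more than other genes. Their counts are therefore not alike where most genes change. Where not given, the cause was not tested.

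Signs of values called otherwise turned as follows, and the cause was not tested. With normexp, exposed minus control became 0.36 for tatC, 0.63 for merD, 0.79 for merP, 0.60 for merT, 0.14 for xseA, 0.00020855 for greA, 0.11 for katA and 0.69 for prfC. Recovered minus exposed became -0.0067 for pilD, -0.30 for merD, -0.12 for merA, -0.47 for merP, -0.42 for NE1111, -0.43 for xseA, -0.13 for xerD, -0.0305 for NE1506, -0.0760 for recG, -0.32 for katA, -0.18 for acrD4 and -0.41 for nth. merA was -0.0231 with the slide as a block and within slide 1. Under quantile scaling and with the authors' values amoB1 was -0.15 and -0.15 in exposed cells, and in recovered cells amoB1 was -0.25 and -0.20, cycA3 -0.0583 and -0.10 and cycA2 -0.17 and -0.18. The toxin-antitoxin list had a mean of 0.35 between recovered and exposed cells, and fry gave its direction as up, while camera placed it below other genes.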

Other observations

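The search for runs of neighbouring genes below was chosen after the data were seen and has no planned test. Genes on the same strand that changed at least 2-fold together lay next to each other in longer runs than in 1000 shuffles of the gene order. The shuffles moved the strand together with the change, so the grouping of same-strand genes along the chromosome was lost in them too. How much of the excess comes from that grouping was not tested. In exposed against control cells the longest run of higher genes held 8 genes (longest in shuffles 6) and of lower genes 8 (7). In recovered against control cells these were 7 (5) and 6 (5), and in recovered against exposed cells 15 (6) and 7 (5). Runs of higher genes in exposed cells included the run from ccmE to bcp with 4 ccm genes for cytochrome c maturation (6 genes, position 832142 to 837542, 1.06 to 2.58 log2). The run from NE1445 to NE1451 with ycf16, annotated as the SufC ATPase, and NE1450, annotated as SufB (7 genes, 1578062 to 1584255), was at 1.41 to 3.38 in exposed and 2.09 to 2.74 in recovered cells.

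Lower runs in exposed cells included the cell wall and division genes from ftsI to murC (8 genes, 1069379 to 1080342, -2.99 to -1.32 log2), the run from NE0605 to plsC, which holds the glycine cleavage genes gcvT and gcvH1 beside cah and others (8 genes, -3.49 to -1.16), and NE1868 to NE1874 with the polyamine transporter genes potA, potB, potC and potD (7 genes, -3.66 to -1.31). In recovered against exposed cells, the ribosomal protein run from rplB to rpsE (15 genes, 455123 to 461834) rose by 1.16 to 2.39 log2. The run from ctaB to coxA with cytochrome oxidase genes (7 genes) rose by 1.23 to 2.67, and the ATP synthase run from atpF to atpC (6 genes) by 1.08 to 1.94. The run from NE1538 to NE1542 (4 genes) was at -5.68 to -2.68.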
